A study of Mus musculus with 6 samples.

How the data were processed

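The series holds ATAC-seq data from lineage-depleted mouse bone marrow labelled as hematopoietic stem and progenitor cells, 3 libraries of inv(16) with heterozygous Smc3 (Smc3 het) and 3 of inv(16) with wild-type Smc3 (Smc3 wt). Groups were taken from the sample titles. Per the submitters' processing notes, reads were aligned with Bowtie2 to mm10 and peaks were called with MACS2. Versions, filters, the Tn5 shift, the extension size, any control track and whether the 3 libraries of a genotype were pooled are not given in the sources used here. The authors deposited 1 list per genotype in the 10-column narrowPeak layout without a header. The lists were tied to the genotypes by the peak names in them.

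Each list gives a position, a score, a fold, a p-value and a summit per peak. The deposited integer score was 10 times the -log10 q, rounded down, in 99.996% of Smc3 het and 99.993% of Smc3 wt rows. The deposited fold is a ratio of the summit over the background of that list, as the authors' peak caller gave it. The deposited -log10 p and -log10 q are those of the peak caller, and the lowest -log10 q was 1.30 in Smc3 het and 1.33 in Smc3 wt, just within a q of 0.05. These values belong to the peak in its own list and were used to describe, rank or filter peaks within it. No row overlapped or touched another row of its list.

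The files hold no read counts, so depth is unknown. The fold values fell on even steps, as they do when fold is pileup plus 1 over background plus 1. The step gave a genome-wide background of 10.6 for Smc3 het and 8.65 for Smc3 wt. With a whole-number pileup, the Poisson upper tail matched the deposited -log10 p to within 0.01 for 99.7% and 99.4% of peaks. The pileup at the summit was at least 23 in Smc3 het and 21 in Smc3 wt, with medians of 38 and 41. On simulated peaks the recovery gave the true pileup for 100% of them. By default MACS2 sets its smallest peak width to the fragment length, and the narrowest peaks were 138 bp and 208 bp. If that default was used, the background per bp of extension, which follows the number of reads, was 1.85 times higher in Smc3 het.

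Overlap was counted at 1 bp or more in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the overlap functions were tested on simulated intervals against bedtools 2.31.1. For chance overlap the Smc3 wt peaks were placed at random 100 times between the first and last peak position of their chromosome. For equal list length the Smc3 het list was cut to the length of the Smc3 wt list by -log10 q. Shares carry exact Clopper-Pearson 95% intervals.

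Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly of mm10, which gives spans but neither strand nor exons. The planned assignment to the nearest transcription start and the split into promoter, exon and intron were therefore replaced by the nearest gene span and by positions within 1 kb of either gene end. The 21888 genes used were protein-coding, with 1 list member of another class, on chromosomes 1 to 19, X and Y. Genes placed at the very start of chromosome 1, such as Ren2 (159748 to 169505), had 0 peaks in both lists. Their positions were not checked, and they count among the genes without a peak. The 326 Smc3 het and 137 Smc3 wt peaks on unplaced scaffolds had no gene. All 286 genes of the 19 lists were found. Lists, motifs, named-gene rule, tests and alternatives were fixed before the data were examined, except where the text says otherwise. Motif content was planned but no genome sequence was used here.

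For each list, the mean number of peaks found in 1 list alone was ranked among 10000 random lists, drawn with replacement within 10 classes of gene length. In 200 simulated lists of 15 genes without effect 6.5% fell outside the central 95%, and 100% of lists with 3 times the peaks were found above it. Genes share loci and are not independent replicates, so these ranks are descriptions. The text names Smc3, Fli1, Cbfb, Myh11 and Runx1, then from each list up to 3 members with most peaks in the Smc3 het list alone and 1 with most in the Smc3 wt list alone. It adds the 5 genes of each kind over all genes and the 5 most significant peaks of each list alone. A test over replicates, a replicate block and leaving out libraries were planned only for values per library, which the files analysed do not hold. The alternatives were stricter thresholds, other overlap rules, other ranks, other gene assignments and other matching of random lists.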

Results

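Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in hematopoietic stem and progenitor cells from lineage-depleted mouse bone marrow. All 6 libraries were labelled inv(16). In human acute myeloid leukemia this inversion joins the core-binding factor gene CBFB to the smooth muscle myosin gene MYH11. The mouse genes Cbfb and Myh11 lie on chromosomes 8 and 16. Smc3, which encodes a ring subunit of cohesin, was heterozygous in 3 of the 6 libraries (Smc3 het) and wild type in the other 3 (Smc3 wt). Per the labels, the treatment was viral transduction and induction with tamoxifen. The study asked, per its title, how cohesin haploinsufficiency and inv(16) act together on programs of Fli1, an ETS-family transcription factor of blood stem cells. The deposited data were 1 peak list per genotype on mm10, with no values per library, so no difference below has a replicate check and none carries a p-value. Intervals on shares of peaks are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Read depth is unknown. The background pileup recovered from the authors' fold and p-values was 10.6 for Smc3 het and 8.65 for Smc3 wt. Per bp of the narrowest peak it was 1.85 times higher in Smc3 het, which follows the reads only if the peak caller's default width was used.

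The targeted gene and the genes named in the study's design were examined first. Smc3 (chromosome 19, 53600396 to 53645831) had a peak over 1 end of the gene in both lists, at 53599874 to 53600581 in Smc3 het with an authors' fold over background of 9.62 and at 53599876 to 53600513 in Smc3 wt with 6.58. Such a peak does not report the number of intact alleles, so it checks no label. Fli1 (chromosome 9, 32422204 to 32543432) had 13 peaks in the Smc3 het list and 2 in the Smc3 wt list, and 12 of the 13 were in the Smc3 het list alone. The strongest of these lay 13086 bp outside the gene, at 32556181 to 32556633, with a -log10 q of 20.2, and the next at 32508801 to 32508971 inside the gene, with 17.2. Both lists held a peak inside Fli1 near its end at 32543432 (32540172 to 32540791 in Smc3 het). The Smc3 wt list held 1 further peak there, at 32541064 to 32541326 with a -log10 q of 3.51. It overlapped no Smc3 het peak but lay within 500 bp of the one just named. At the equal list lengths described below, 3 of the 3 Smc3 het peaks at Fli1 and 2 of the 2 Smc3 wt peaks had no counterpart. The shared Smc3 wt peak lost its counterpart there because the cut removed the Smc3 het peak. Runx1 (chromosome 16, 92601466 to 92826074), the DNA-binding partner of Cbfb, had 29 peaks in Smc3 het and 9 in Smc3 wt, and 20 of the 29 were in the Smc3 het list alone. Cbfb (chromosome 8, 105170674 to 105217989) had 2 peaks in each list, all shared. Myh11 (chromosome 16, 14194527 to 14292188) had 2 peaks, both inside the gene and in the Smc3 het list alone.

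**Figure D1:**
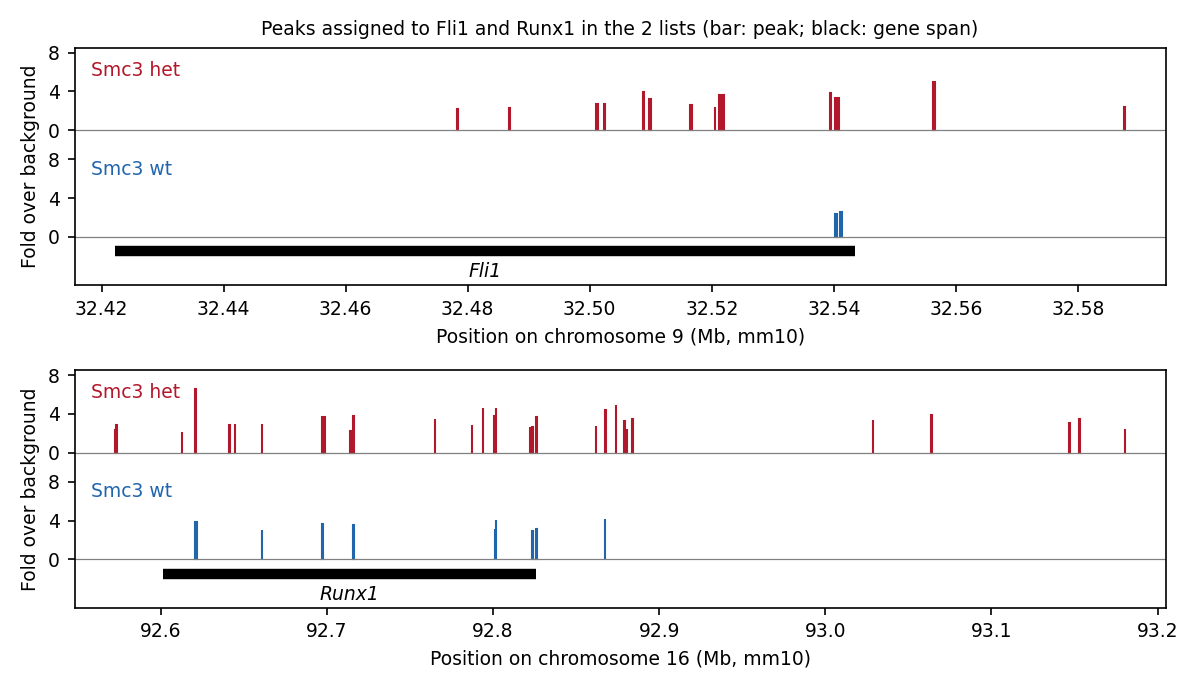
Peaks assigned to Fli1 on chromosome 9 and Runx1 on chromosome 16. The x axis is the mm10 position in Mb, bar height is the authors' fold over background in each list (Smc3 het in red, Smc3 wt in blue), narrow bars are drawn with a minimum line width, and the black bar is the gene span. Fli1 had 13 Smc3 het and 2 Smc3 wt peaks, and Runx1 had 29 and 9.

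The Smc3 het list held 47233 peaks over 19.95 Mb and the Smc3 wt list 14830 over 7.27 Mb, a ratio of 3.18 in number. Nearly the whole Smc3 wt list lay within the Smc3 het list. Of the Smc3 wt peaks, 14397 (97.1%, interval 96.8 to 97.3) overlapped a Smc3 het peak by at least 1 bp, against 1.72% on average when the Smc3 wt peaks were placed at random on their chromosomes 100 times (highest 1.97%). Of the Smc3 het peaks, 14269 (30.2%, 29.8 to 30.6) overlapped a Smc3 wt peak and 32964 were found in the Smc3 het list alone. Only 433 peaks were found in the Smc3 wt list alone. Over each whole list the median width was 418 bp in Smc3 wt and 318 bp in Smc3 het, and the narrowest peak was 208 bp and 138 bp. These medians do not compare the same sites. Shared peaks at Smc3 (708 bp in Smc3 het, 638 bp in Smc3 wt), Fli1, Cbfb and Runx1 were wider in Smc3 het. The exception was a Runx1 site, with 565 bp in Smc3 het and 890 bp in Smc3 wt. In all, 12234 Smc3 het peaks were narrower than any Smc3 wt peak. The ratio of peak numbers was 1.92 among peaks with a fold of at least 5.

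The share of Smc3 het peaks that Smc3 wt also held was lower at lower significance. In the most significant decile of the Smc3 het list 98.2% of peaks were shared, in the third decile 51.7% (50.2 to 53.1), in the fifth 16.5% and in the last 0.995%. Within each of the first 9 deciles, peaks at a gene end were shared more often than other peaks. In the third decile 68.9% (66.3 to 71.3) of gene-end peaks were shared and 44.5% (42.8 to 46.2) of the others.

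**Figure D2:**
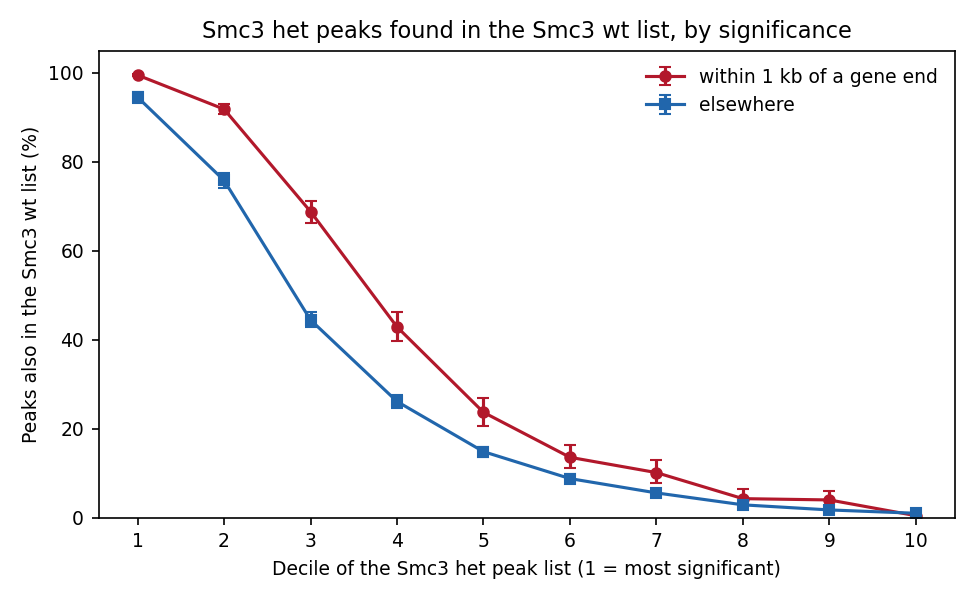
Share of Smc3 het peaks also found in the Smc3 wt list (y axis, percent) by decile of the Smc3 het list ordered by the authors' -log10 q (x axis, 1 is the most significant). Red circles are peaks within 1 kb of a gene end and blue squares all others, on chromosomes 1 to 19, X and Y, and error bars are exact 95% binomial intervals. In the third decile the values were 68.9% and 44.5%.

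To compare lists of equal length, the Smc3 het list was cut to its 14830 most significant peaks. Of these, 11290 (76.1%, 75.4 to 76.8) overlapped a Smc3 wt peak, and 11475 Smc3 wt peaks (77.4%, 76.7 to 78.0) overlapped one of them. Unmatched peaks numbered 3527 in Smc3 het and 3289 in Smc3 wt on chromosomes 1 to 19, X and Y, near-equal numbers that equal list lengths impose. For Smc3 wt, unmatched means without a counterpart in the cut Smc3 het list. Most of these Smc3 wt peaks overlapped a Smc3 het peak that the cut had removed, since only 433 were alone in the full lists. With the 7415 most significant peaks of each list, 84.9% of the Smc3 het peaks and 85.0% of the Smc3 wt peaks were shared.

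Shared peaks lay mostly at genes' ends, and peaks of the Smc3 het list alone lay mostly away from them. A gene end here is a position within 1 kb of either end of a protein-coding gene, because the gene table used gives no strand and start sites could not be told from 3′ ends. Of the shared Smc3 het peaks 51.5% (50.6 to 52.3) lay at a gene end, 26.4% elsewhere inside a gene and 22.1% between genes. Of the peaks in the Smc3 het list alone 12.8% (12.4 to 13.1) lay at a gene end, 42.5% inside a gene and 44.7% between genes. Random positions gave 3.19% at a gene end. Of the 426 peaks in the Smc3 wt list alone on these chromosomes 8.45% (5.99 to 11.5) lay at a gene end, a lower share than in the Smc3 het list alone. At equal list length the whole lists differed by less than their counting error, with 49.5% (48.6 to 50.3) of Smc3 het and 49.9% (49.1 to 50.8) of Smc3 wt peaks at a gene end. Counted by gene, 8200 of 21888 genes had a gene-end peak in both lists, 3104 in Smc3 het only, 58 in Smc3 wt only and 10526 in neither.

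Genes of blood transcription factors had more peaks per gene in the Smc3 het list alone than random lists of genes. Each peak was assigned to the nearest protein-coding gene, and a list's mean number of such peaks per gene was ranked among 10000 random lists of the same size and gene lengths. These percentiles describe the 2 peak lists and are not p-values. The 15 ETS and stem-cell transcription factors had 7.40 such peaks per gene, against 2.36 in random lists, which was above all 10000 of them. They were also high for all Smc3 wt peaks (percentile 99.6), as were the core-binding factor (98.8), progenitor (99), kinase and RAS (98.5) and interferon and inflammatory (97.6) lists that follow. Of the 15 genes 13 had at least 1 such peak and 1, Fli1, had a peak in the Smc3 wt list alone, within 500 bp of a Smc3 het peak. Runx1 had 20 such peaks, Etv6, an ETS repressor, had 15 of its 17 peaks in the Smc3 het list alone, and Erg, a stem-cell ETS factor, 14 of 17. The list of 6 core-binding factor and inv(16) partner genes, which shares Runx1 with the first list, had 8.83 peaks per gene against 3.17 (percentile 99.8), led by Runx1, Runx3 (17 of 19) and Runx2 (11 of 14). It was inside the central 95% of random lists, at 97.0, when only peaks in gene bodies and 5 kb around them were counted. The 30 stem-cell and self-renewal genes had 3.67 per gene against 2.16 (percentile 99.6), and 26 of them had at least 1. Myc, the proliferation factor, had 17 of its 21 peaks in the Smc3 het list alone, the RNA-binding protein gene Msi2 10 of 11 and Angpt1, a ligand of stem cells' Tek receptor, 9 of 11. Prdm16 had 1 peak in each list, and the 2 did not overlap, but the Smc3 het peak was within 500 bp of a Smc3 wt peak. Far fewer unmatched peaks were left at equal list length, 2 in Smc3 het and 2 in Smc3 wt at Runx1, 3 and 0 at Etv6, 0 and 0 at Erg, 1 and 1 at Runx3 and 0 and 1 at Runx2. Smc3 wt then had more at Myc (2 and 4), Msi2 (0 and 1) and Angpt1 (1 and 2). In the full lists, however, every Smc3 wt peak at these genes overlapped a Smc3 het peak. Within gene bodies and 5 kb around them the Smc3 het list alone had 8 peaks at Runx1, 6 at Runx3 and 3 at Myc.

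The 20 receptor tyrosine kinase, RAS and JAK-STAT genes had 4.05 peaks per gene in the Smc3 het list alone against 2.10 in random lists (percentile 99.8), and 19 of the 20 had at least 1. With gene bodies and 5 kb around them this list was at 97.0, inside the central range. Bcl2, which blocks apoptosis, had 10 of 12, Dusp6, a phosphatase of ERK, 9 of 12 and the receptor gene Kit (chromosome 5, 75574987 to 75656722) 8 of 9. Pim1 had 1 peak in the Smc3 wt list alone. The 20 interferon and inflammatory response genes had 2.55 per gene against 0.982 (percentile 99.9), and 14 had at least 1. They were at 87.7, inside the central range, when random lists were matched on the number of Smc3 wt peaks instead of gene length. The NF-κB subunit gene Nfkb1 had 12 of 12, Tnfaip3, an inhibitor of NF-κB, 9 of 12 and the cytokine gene Il6 5 of 5. The 18 cell cycle regulators had 2.22 against 1.42 (percentile 93.7), with 11 of 19 at Cdk6, 6 of 9 at the cyclin gene Ccnd2 and 6 of 11 at Cdkn1a. The unmatched peaks in Smc3 het and Smc3 wt at equal list length were 2 and 1 at Bcl2, 3 and 0 at Dusp6, 4 and 0 at Kit, 2 and 0 at Nfkb1, 1 and 0 at Tnfaip3, 2 and 0 at Il6, 2 and 1 at Cdk6, 1 and 2 at Ccnd2 and 0 and 1 at Cdkn1a. When only gene bodies and 5 kb around them were counted, the full Smc3 het list alone had 2 peaks each at Dusp6 and Kit. It had 1 each at Tnfaip3 and Il6 and 3 each at Ccnd2 and Cdkn1a.

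Among markers of cell types the marrow could hold, those of monocytes and of granulocyte-monocyte progenitors lay above the central range with random lists matched on gene length. The 14 monocyte and macrophage markers had 3.93 peaks per gene in the Smc3 het list alone against 1.34 (percentile 99.9), and 8 of the 14 had a gene-end peak in Smc3 het only. Ly86 had 13 of its 14 peaks in the Smc3 het list alone, Klf4, a monocyte transcription factor, 7 of 9 and the chemokine receptor gene Cx3cr1 6 of 6. The 14 granulocyte-monocyte progenitor markers had 2.36 against 0.968 (percentile 99.2), with 7 of 11 at Fcgr3, 6 of 6 at Irf8 and 3 of 4 at Cebpa, while Csf2rb had 2 Smc3 het peaks and 1 Smc3 wt peak, none of them overlapping. Unmatched peaks at equal list length in Smc3 het and Smc3 wt were 2 and 0 at Ly86, 4 and 0 at Klf4, 1 and 0 at Cx3cr1, 4 and 0 at Fcgr3 and 0 and 0 at Irf8 and Cebpa. In the gene bodies and 5 kb around them the Smc3 het list alone had 3 peaks each at Klf4 and Fcgr3 and 0 at Ly86, Irf8 and Cebpa. With matching on Smc3 wt peaks, the progenitor list was at 53.2, inside the central range. Other lineages lay inside the range with matching on gene length, but stromal and endothelial markers were at 99.6 with matching on Smc3 wt peaks. Megakaryocyte markers were at 99.7 with gene bodies and 5 kb around them. With matching on gene length the percentile was 94.9 for megakaryocyte markers (Itgb3 8 of 8, Vwf 7 of 9, Gfi1b 4 of 4), 91.2 for dendritic cell markers (Ciita 4 of 4, Siglech 4 of 4), 95.3 for stromal and endothelial markers (Cxcl12 5 of 6, Pecam1 5 of 5) and 80.5 for T and NK cell markers (Gata3 9 of 12, Tcf7 4 of 4). It was 56.2 for mast cell, basophil and eosinophil markers (Hdc 4 of 4, Il1rl1 3 of 5), 32.3 for erythroid markers (Car2 5 of 6, Nfe2 2 of 3), 31.7 for neutrophil markers (Mmp9 3 of 4, Retnlg 2 of 2) and 7.97 for B cell markers (Ebf1 4 of 4, Dntt 2 of 2). Here too the number was smaller within gene bodies and 5 kb around them at Car2 (1), Gata3 (2), Tcf7 (1), Siglech (1), Gfi1b (2), Ebf1 (2), Dntt (1), Cxcl12 (0) and Retnlg (0). The neutrophil gene S100a8 had 1 peak, in the Smc3 wt list alone.

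Cohesin genes had fewer such peaks than random lists of the same gene lengths. The 15 genes of the cohesin complex and its regulators had 1.00 peak per gene in the Smc3 het list alone against 2.5 in random lists (percentile 0.32), with 3 of 6 at the release factor gene Wapl, 2 of 3 at Pds5a and 2 of 2 at Mau2. This call was lost with matching on Smc3 wt peaks (16.7), with gene bodies and 5 kb around them (5.22), with matching on nearest genome (4.42) and at equal list length (7.97). The 14 housekeeping genes lay at percentile 74.7 (Ywhaz 7 of 14, Actb 3 of 5), at 97.2 at equal list length and there at 98.2, above the range, with matching on nearest genome, and at 2.9 with matching on Smc3 wt peaks. The 16 genes of unrelated tissues lay at 95.3, with 14 of 14 peaks at Pou3f2, a neural factor gene, 5 of 6 at Pax6 and 2 of 3 at Sox2. Within gene bodies and 5 kb around them the numbers were 0 at Ywhaz, Pou3f2 and Sox2, 1 each at Actb, Wapl and Pds5a and 2 at Pax6, and Wapl had 0 and Mau2 1 when peaks within 500 bp counted as shared. Of the 19 lists 8 lay outside the central 95% of random lists, 7 above and 1 below, where 0.95 are expected by chance. Gene families grouped by symbol, given below, lay outside about as often: 8 of 18, 4 above and 4 below, with 0.9 expected. Lying outside random lists is thus not particular to these 19 lists. With random lists matched on the length of genome nearest to each gene, the genes of unrelated tissues moved to percentile 48.5 and the megakaryocyte markers to 99.9.

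**Figure D3:**
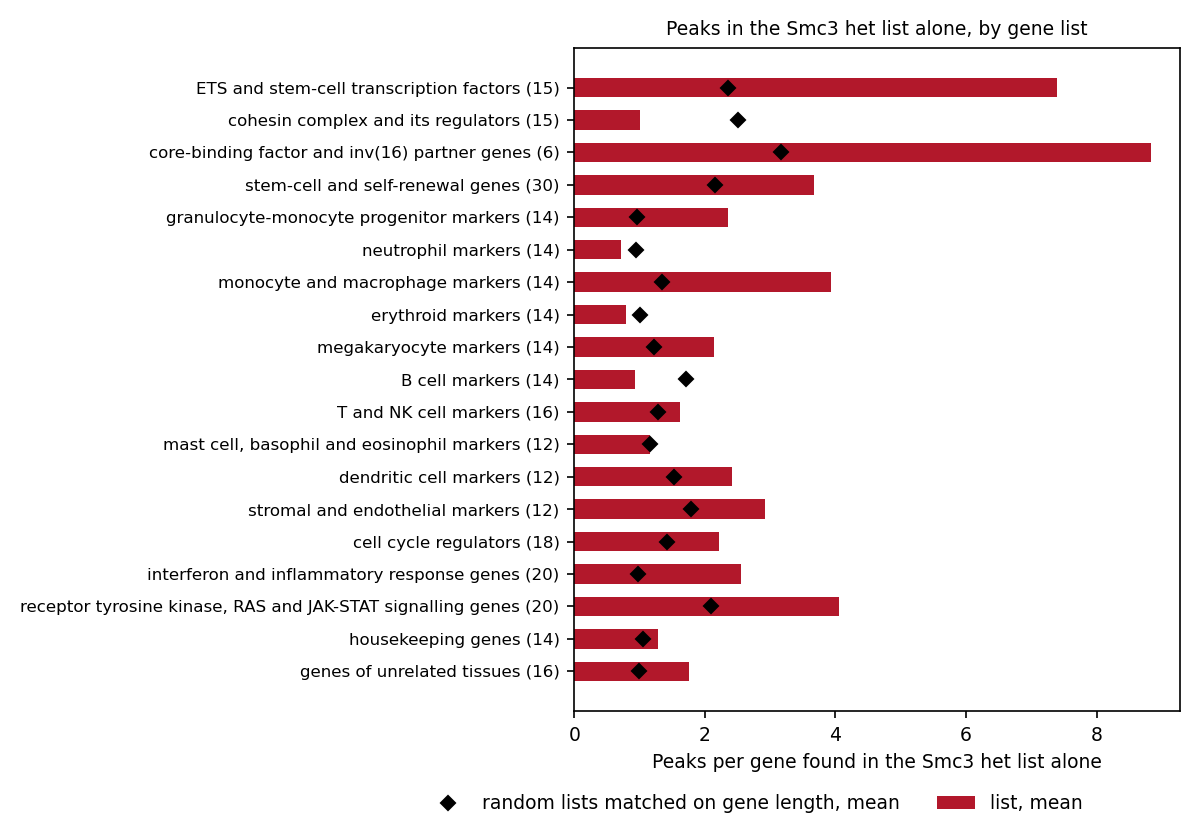
Mean number of peaks per gene found in the Smc3 het list alone (x axis) for each of the 19 gene lists (y axis, number of genes in parentheses). Bars are the list's mean and black diamonds the mean of 10000 random lists matched on gene length. The ETS and stem-cell transcription factors had 7.40 against 2.36 and the cohesin genes 1.00 against 2.5.

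At equal list length, 5 of the 19 lists lay above the central range, with percentiles of at least 99.6: the ETS and stem-cell transcription factors, the granulocyte-monocyte progenitor and monocyte and macrophage markers, and the 2 signalling and inflammatory lists. The stem-cell and self-renewal genes were at 97.49, at the edge of the range, and the core-binding factor genes at 78.0. With matching on Smc3 wt peaks as well, the progenitor markers (93.6) and interferon and inflammatory genes (92.6) were inside the range. Peaks went unmatched in both directions under the cut. For Smc3 wt peaks unmatched in the cut Smc3 het list 1 gene list, the cell cycle regulators, lay above the range (98.0). In the full lists the cell cycle regulators had 0 peaks in the Smc3 wt list alone. Of the 21 unmatched peaks at ETS and stem-cell transcription factors 15 were in Smc3 het and 6 in Smc3 wt, a Smc3 het share of 71.4% (47.8 to 88.7) against 51.7% over all genes. The share was 78.6% (49.2 to 95.3) for monocyte and macrophage markers, 70.8% (48.9 to 87.4) for the kinase, RAS and JAK-STAT genes and 52.0% (31.3 to 72.2) for the stem-cell and self-renewal genes. These intervals all included the share over all genes, which equal list lengths hold near an even split, and most other lists had too few unmatched peaks to compare.

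Over all genes, the 5 with most peaks in the Smc3 het list alone were 9530057J20Rik (37 of 53), the imprinted gene Snrpn (34 of 53), Zfp978 (33 of 49), Zfp993 (32 of 39) and Zfp386 (30 of 40). Within gene bodies and 5 kb around them, where a peak can count for overlapping genes, the numbers were 12, 2, 23, 34 and 0. Unmatched peaks at equal list length in Smc3 het and Smc3 wt were 2 and 8 at 9530057J20Rik, 1 and 12 at Snrpn and 0 and 15 at Zfp978. They were 2 and 10 at Zfp993 and 7 and 4 at Zfp386, so Smc3 wt then had more at all but Zfp386. In the full lists, the Smc3 wt peaks found alone at these 5 genes numbered 1, 2, 3, 4 and 0, in the same order. The 5 with most peaks in the Smc3 wt list alone were LOC665918 (7 of 7), Gm7592 (5 of 16), Zfp993 (4 of 11), Gm10354 (3 of 13) and Gm21190 (3 of 12). Several of these are members of multicopy families, where reads can be shared between copies, so their peaks are uncertain. The 5 most significant peaks of the Smc3 het list alone were all narrower than the narrowest Smc3 wt peak. The first lay on chromosome 13 at 77438910 to 77439056 (147 bp, fold 38.5) inside 2210408I21Rik. The others were on chromosome 6 at 9889948 to 9890152 (205 bp), on chromosome 13 at 120321444 to 120321638 (195 bp), on chromosome 16 at 93789190 to 93789383 (194 bp) inside Dop1b and on chromosome 17 at 67741362 to 67741568 (207 bp) inside Lama1. The 5 most significant peaks of the Smc3 wt list alone were all on chromosome Y, at 11857871 to 11858483 (fold 15.7), 142623 to 143294 (9.84), 258322 to 259454 (8.03), 260974 to 261684 (7.50) and 145319 to 146367 (6.29).

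The excess of Smc3 het peaks was spread over the genome. The Smc3 het to Smc3 wt ratio of peak numbers was between 2.95 and 3.38 on the 19 autosomes and 3.19 over all chromosomes. On chromosome X it was 4.07 (3.59 to 4.61), with 1281 and 315 peaks, and on chromosome Y 2.63 (1.76 to 4.0), with 92 and 35. At equal list length the ratio was 0.946 (0.805 to 1.11) on chromosome X and 0.600 (0.332 to 1.06) on chromosome Y, with 21 and 35 peaks.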

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

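No paired analysis was possible because each genotype has 1 peak list and no values per library, so the replicate block, the count models, leaving out libraries and the filter on low counts were not run; motif alternatives were not run without a genome sequence. The settings at the background or width of the other list, without scaffolds and folds of at least 10, and with random lists matched on nearest genome were chosen after seeing the data. The Smc3 het list stayed the longer one in each setting that counted peaks: a -log10 q of at least 5 left 28558 Smc3 het peaks and a ratio of 2.56, a fold of at least 5 left 7603 and 3957 (1.92), the Smc3 wt background gave 2.97 (2.43 per bp of minimum width) and the Smc3 wt minimum width 2.36, each against 3.18. The shares of Smc3 het and Smc3 wt peaks found in the other list were 24.4% and 77.6% with 50% reciprocal overlap, 32.0% and 97.6% within 500 bp, 38.5% and 98.8% with a -log10 q of at least 5 in both lists, and 48.0% and 99.6% against the whole other list. With windows of 250 bp around summits 94.4% of Smc3 wt peaks were shared, at the Smc3 wt background 32.3% of Smc3 het peaks (per bp of minimum width 39.0%, and 95.8% of Smc3 wt peaks), with the minimum width 40.0% and 95.6%, and without scaffolds and folds of at least 10, 29.6% of Smc3 het peaks. At equal list length the shares were 74.3% and 75.4% ranked by fold, 84.9% and 85.0% for the 7415 most significant peaks of each list, and 30.2% and 30.7% with random Smc3 het subsets, a fall that follows from drawing weaker peaks. Gene-end shares of the peaks in the Smc3 het list alone and the shared peaks were 22.4% and 59.0% within 3 kb and 19.7% and 58.8% at equal list length, so the order held in both. The ratio on chromosome X was 0.946 at equal list length. Lists outside the central range numbered 5 at equal list length, and 6 to 8 in the other settings, against 8. Of the percentiles and peak numbers of single lists and genes, 21 stayed within 1.5 times or on their side at equal list length and 71 did not, since fewer Smc3 het peaks enter; the numbers were 50 and 42 with gene bodies and 5 kb around them, and 88 and 4 with the 500 bp rule. The depth of the libraries is unknown, so absence from the Smc3 wt list does not show closed chromatin.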

Other observations

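The tests at the Smc3 wt background, alone and with weaker enrichment, and of the chromosome Y genes were chosen only after the results they bear on had been seen. So was the use of chromosome X at equal list length, a planned setting, as a test. Gene families defined by their symbols, chosen after the main lists had been seen but before their own values, gave further groups. Of 18 families 8 lay outside the central 95% of random lists matched on gene length, where 0.9 are expected by chance. Those above the range were no longer so with random lists matched on the number of Smc3 wt peaks. SOCS and dual-specificity phosphatase genes, feedback inhibitors of cytokine and MAP kinase signalling, had 2.55 peaks per gene in the Smc3 het list alone against 1.1 in random lists (percentile 99.9), with percentiles of 99.4 at equal list length and 96.1 with matching on Smc3 wt peaks. KLF factor genes had 3.71 against 1.51, chemokine and chemokine receptor genes 1.56 against 0.882 and zinc finger protein genes 1.77 against 1.37. At equal list length KLF genes were at 93.9 and zinc finger genes at 82.6, inside the range, and with matching on Smc3 wt peaks the 3 families were at 92.4, 86.9 and 63.6. SOCS and phosphatase, KLF and zinc finger genes were also high for Smc3 wt peaks (98.3, 99.6 and 100). Chemokine genes stood at percentile 99.5 for these peaks but at 16.3 for Smc3 wt peaks. Below the range, for these peaks and for Smc3 wt peaks, lay 4 families: olfactory receptors 0.208 against 0.460, vomeronasal receptors 0.433 against 0.759, keratins 0.245 against 0.914 and cytochrome P450 genes 0.727 against 1.34. Voltage-gated potassium channels (77.0), cadherins and protocadherins (60.4) and solute carriers (88.7) lay inside the range, and at 99.99, 100 and 99.8 with matching on Smc3 wt peaks.

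Ribosomal protein and histone genes held more Smc3 wt peaks than random lists. Ribosomal protein genes had 0.948 Smc3 wt peaks per gene against 0.415 in random lists and histone genes 0.701 against 0.162, but both lay inside the central range for peaks in the Smc3 het list alone (percentiles 32.4 and 16.1). With matching on Smc3 wt peaks both were below all random lists, at percentile 0. The 39 HOX cluster genes had 1 Smc3 wt peak among them and 29 peaks in the Smc3 het list alone. With gene bodies and 5 kb around them, the HOX genes moved from percentile 25.9 to 99.4 and the histone genes to 99.91. A peak can then count for several neighbouring genes, so genes in clusters can share the same peaks. At equal list length the HOX genes had 0 peaks in Smc3 het alone and were at 1.3.

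The first pattern is the longer Smc3 het list. A lower background in the Smc3 wt data is argued against as the whole cause, since 44112 of the 47233 Smc3 het peaks would still pass with their pileups scaled down to the Smc3 wt background, fold over it kept, and at the lowest Smc3 wt p-value, and 36064 at the lower background per bp of minimum width. Of the 2000 strongest Smc3 het peaks, 1960 were found in Smc3 wt. Their excess over background was lower in Smc3 wt, with a median ratio of 0.706 (quartiles 0.627 and 0.790). These peaks were picked by their strength in Smc3 het, and the extension sizes may differ. Weaker enrichment of the same sites in Smc3 wt is therefore not shown by the ratio alone. Scaling every Smc3 het peak by this median ratio left 29004 peaks, above the bound of 22245 set beforehand. At the background per bp of minimum width the scaling left 21228 (17607 at the lower quartile), so that bound, which took no account of extension size, excludes nothing here. Weaker enrichment together with fewer reads may thus account for part of the difference. With both, 81.5% of the third decile were predicted in Smc3 wt under 1 ratio distribution for all peaks, but 51.5% were found. That prediction set no minimum width, while the narrowest Smc3 wt peak was 208 bp, so it can overstate the shortfall. Weaker enrichment and fewer reads cannot be told apart from an effect of Smc3 genotype with 1 list per genotype and the extension size not given.

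The second pattern is the small share of gene ends among peaks in the Smc3 het list alone (12.8%). Weaker peaks do lie away from gene ends more often, but shared peaks weighted to the same significance lay at a gene end in 22.6% of cases against 13.1%, higher in 18 of 18 classes of significance, which held 89.7% of the peaks in the Smc3 het list alone. Weighting to both significance and width gave 23.6% against 13.7% for the 70.5% of peaks that could be matched, which argues against narrow peaks being missed as the whole cause. At equal list length the unmatched peaks lay at a gene end in 19.7% of cases in Smc3 het and 20.98% in Smc3 wt. Most of these Smc3 wt peaks overlapped Smc3 het peaks below the cut. Those 2 shares therefore cannot tell whether the small share is particular to Smc3 het. In the full lists, 8.45% of the 426 peaks in the Smc3 wt list alone lay at a gene end, also a small share. Peaks away from gene ends may differ more between any 2 lists, and neither that nor an effect of Smc3 genotype was tested.

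The third pattern is the ratio of 4.07 on chromosome X. The ratio relative to all chromosomes was 0.943 at equal list length, consistent with chromosome X peaks ranking low in both lists; the share of peaks on chromosome X was 2.51 times higher in the last than in the first decile of the Smc3 het list, and in Smc3 wt it was 2.76% and 0.944%. That trend within a list does not by itself speak about the sex of the mice, since both lists show it. Pools that differ in the sex of the mice are argued against by the 6 chromosome Y genes with widely expressed relatives on chromosome X (such as Kdm5d, Eif2s3y and Ddx3y), of which 0 had a gene-end peak in either list, while 5 of their chromosome X relatives had one in both. The 5 most significant peaks of the Smc3 wt list alone nevertheless lay on chromosome Y, away from these genes, and at equal list length chromosome Y had 21 Smc3 het and 35 Smc3 wt peaks, so the sex of the mice stays partly open.

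On chromosome Y the Smc3 wt list alone held 7 peaks nearest to LOC665918, and its strongest peak alone in the genome lay at 11857871 to 11858483 with a fold of 15.7, against 0 Smc3 het peaks nearest to LOC665918. The most significant shared peak was the same region in both lists, on chromosome 2 at 98666258 to 98667321 in Smc3 het and 98666260 to 98667320 in Smc3 wt, 1035278 bp from the nearest gene. Regions of very high signal were kept in the main comparison, and whether this one is an artifact was not tested.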
